A study of Mus musculus with 13 samples.

How the data were processed

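RNA was measured in 13 libraries of endothelial cells from the livers of mice at postnatal days 3 (P3) and 42 (P42). The cells were freed by enzymes and sorted with magnetic beads, per the labels. Knockout mice carried Lyve1-Cre and floxed alleles of Heg1, and controls were floxed mice. The labels name Cre in no control, so loss of Heg1 and presence of Lyve1-Cre cannot be told apart. Genotype below stands for both. The groups held 3 P3 controls, 4 P3 knockouts, 3 P42 controls and 3 P42 knockouts. The labels do not say whether each library is a separate animal, so p-values measure the spread between these samples, which could be partly technical. A protocol text in the labels names P3 for all samples, while the titles separate P3 from P42, and the titles were followed.

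The deposited values are FPKM (fragments scaled by transcript length and by mapped fragments) with 2 decimals. HISAT2, StringTie and DESeq2 and the build mm10 are named in the submitters' processing notes. Their versions, settings and gene annotation are not given in the sources used here, and neither is which step used which tool. The deposited values covered 31598 entries at P3 and 33589 at P42, of which 31406 symbols were shared. The tables may therefore have been made apart, and a level set across ages rests on their being comparable. Of symbols listed more than once (188 at P3, 220 at P42), the row with the highest mean was kept. Gene positions are from RefSeq on GRCm38.p6, the same build as mm10, which held 29288 of the P3 symbols and 31168 of the P42 symbols.

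The files hold no read counts, so a count test could not be used. The spacing of low FPKM values gave a rough depth of 12.4 to 17.1 M fragments (M, mega) in 12 libraries and 8.1 M in P42 control 2. Only 36.7 to 53.3 percent of the low values lay within 0.15 of a whole number of fragments, so these depths are estimates and no interval was made from them.

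Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) on log2(FPKM + 1). Genes needed a mean FPKM of at least 1 over the fitted libraries, and calls an adjusted p (Benjamini-Hochberg) below 0.05. Changes are on the log2(FPKM + 1) scale, which understates changes of low genes. The comparisons were knockout against control at each age, the genotype by age interaction, and P42 against P3 in controls. An effect averaged over both ages in 1 fit was added after the data were seen. The other fits, the gene lists, the alternatives and the rule for named genes were set before the data were examined. Exceptions are the tests and alternatives given below as added or chosen later.

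The 35 gene lists covered endothelial kinds, other liver and blood cells, signalling pathways, stress and metabolism. They were tested with camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, added later. Of the 588 genes in them, 3 were absent from the tables. Named genes were Heg1, Lyve1, Klf2, Klf4, Wnt2, Wnt9b and Rspo3, and the 10 largest called rises and falls per genotype comparison whose groups did not overlap. Where fewer passed, the smallest unadjusted p filled the 10 places, given as values that did not pass. The interaction took 5 per direction, the control age comparison 10, and each list added a few members by smallest p. Predicted genes, clones and pseudogenes were left out.

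Whether equal replicate numbers pair the samples was checked from the correlation of deviations from the group means. At P42 the numbers 1, 2 and 4 gave 0.526, 0.402 and 0.344, each the highest for its control, so by the rule set for this check the numbers pair these samples. The pairing comes from the data, since the labels do not say what a number marks. With so few samples such a match can also arise by chance. Equal numbers also shared their sex by Xist (number 2 female, 1 and 4 male), and the mitochondrial share rose in the order 1, 2, 4 in both groups. These could give such correlations without a pairing, so blocked values depend on an unproven pairing. Blocked values are given where they change a call.

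The limma fits and camera at the preset correlation were tested on simulated data, with independent noise of the real size and a known set of changed genes per run. The other tests were not simulated. At P3 (13120 genes) 66.9 percent of 2-fold and 95.2 percent of 4-fold changes were recovered. At P42 (12838 genes) the shares were 41.8 and 81.0 percent. Real libraries share deviations across genes, which this simulation leaves out. It also changed more genes per run than the genotype comparisons at each age called, which eases the adjusted threshold. The shares in the real data may therefore be lower.

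The alternatives were a pseudocount of 0.1, other filters, 3 other scalings, other variance models, 1 fit over all groups, replicate blocks, covariates for other cell types and for Xist, and leaving out each replicate. Leaving out the mitochondrially encoded genes was added later. Figures were drawn with matplotlib 3.10.9.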

Results

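Liver endothelial cells of Lyve1-Cre;Heg1 floxed mice and floxed controls were compared at 2 ages, in 13 libraries. Heg1 is an endothelial transmembrane receptor of the pathway mutated in cerebral cavernous malformation (CCM). The FPKM sum per library lay between 582952 and 862642, and 12446 to 13158 genes reached an FPKM of 1. Mitochondrially encoded genes held 8.91 to 10.9 percent of the FPKM at P3. At P42 they held 8.37, 16.9 and 27.3 percent in controls and 16.4, 22.3 and 40.5 percent in knockouts.

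Heg1 itself (chromosome 16, 33684384 to 33771576, mm10) was lower in every knockout library than in every control of its age. At P3 it measured 6.43, 7.38 and 6.89 FPKM in controls and 4.28, 4.81, 3.26 and 3.55 in knockouts. The log2 change was -0.68 (SE 0.15, limma adjusted p = 0.445), which did not pass. At P42 the controls measured 17.38, 8.74 and 8.03 FPKM and the knockouts 3.00, 1.84 and 2.28. That log2 change was -1.81 (SE 0.30, limma adjusted p = 0.109), and with the replicate block the adjusted p was 0.0435. Part of the Heg1 signal remained in all knockouts, and the FPKM of the whole gene do not show which exons were read.

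**Figure D1:**
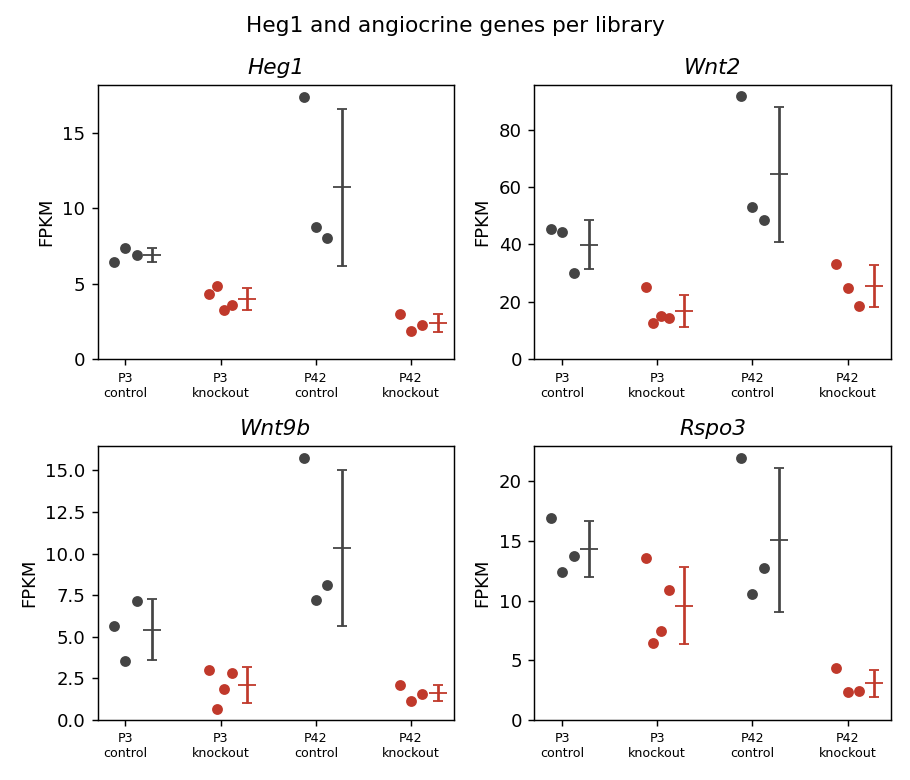
FPKM of Heg1, Wnt2, Wnt9b and Rspo3 on the vertical axis of each panel, with the 4 groups on the horizontal axis; points are libraries, and the bar beside them is the mean with its SD. Heg1 lies between 6.43 and 7.38 in P3 controls and between 3.26 and 4.81 in P3 knockouts, and no P42 knockout reaches the P42 controls.

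At P3, the question was which genes differ in the knockout soon after birth. Trim34b, of the tripartite motif family, rose from 0.20 ± 0.0458 FPKM (SD, n = 3) to 3.92 ± 0.356 (SD, n = 4), a log2 change of 2.03 (SE 0.15, limma adjusted p = 0.00389). Slc26a10, of a family of anion transporters, fell from 65.7 ± 13.1 to 23.4 ± 2.53 FPKM (log2 change -1.44, SE 0.15, limma adjusted p = 0.0427). Tpbgl fell from 17.8 ± 0.756 to 4.54 ± 1.25 FPKM (log2 change -1.80, SE 0.20, limma adjusted p = 0.0427). These 3 were the calls among 13120 genes, and 759 had an unadjusted p under 0.05 where 656 are due by chance. Without P3 control 2 or 3, or knockout 3 or 4, Trim34b alone was called, without control 4 also Slc26a10, and without knockout 2 also Tpbgl. Without knockout 1 the 4 calls were Trim34b, Hsd17b13, Cyp4a14 and Cyp26b1, and Trim34b has near copies nearby, so its FPKM is uncertain.

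No other gene passed at P3. Tgtp2, an interferon-induced GTPase, measured 7.88 ± 1.40 FPKM in controls and 17.8 ± 0.654 in knockouts (log2 change 1.09, limma adjusted p = 0.0534). The interferon-induced gene Oasl1 had a log2 change of 1.27, Mx1 of 0.92, Isg15 of 1.30, Ifit3b of 0.99, Ifit3 of 0.88, Ifi27l2a of 1.03 and the chemokine gene Cxcl10 of 1.09, with limma adjusted p from 0.0534 to 0.338. Phlda3, a p53 target, had a log2 change of 1.47 (limma adjusted p = 0.270). Lower values were seen for Trim12a (-0.87), Trim5 (-0.94), Ly6c1 (-1.44), Ly6a (-0.69), Ceacam1 (-0.65), Rab3b (-1.24), Ikzf3 (-0.55) and Igkv12-38 (-1.64), which did not pass either. The angiocrine genes did not pass: Wnt2 measured 39.9 ± 8.60 FPKM in controls and 16.7 ± 5.74 in knockouts (log2 change -1.23, limma adjusted p = 0.370), Wnt9b had a log2 change of -1.10 and Rspo3 of -0.57. Klf4 (-1.04), Klf2 (-0.17) and Lyve1 (-0.51) did not pass.

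The interferon response list rose at P3: all 25 members were higher, with a median log2 change of 0.72 (camera adjusted p = 7.0e-34), and 20 passed when adjusted over the list alone against 0 over all genes. With an estimated correlation the adjusted p = 0.272. Lists lower in the camera test were venous endothelium (12 of 14 members lower, median -0.46, 4 adjusted over the list alone: Cdh13, Ltbp4, Thbd and Wnt9b), sinusoidal identity (25 of 28 lower, median -0.25), the HEG1-CCM pathway (20 of 22 lower, median -0.12), KLF2/KLF4 and flow-responsive genes (15 of 20 lower, median -0.19) and angiocrine factors (13 of 21 lower, median -0.14). Each of these 5 calls is lost with an estimated correlation (adjusted p = 0.627). P3 knockout 1 lay among or above the controls in the venous, sinusoidal, flow-responsive and angiocrine lists, while the other knockouts lay below all controls. Its venous list mean, relative to the mean of the age, was 0.26, against 0.18 to 0.28 in controls. Its flow-responsive one was 0.26, against 0.11 to 0.25. The HEG1-CCM pathway groups did not overlap. Markers of other cells moved as well: erythroid (18 of 18 higher, median 0.37), hepatocyte (21 of 22, median 0.34), periportal (12 of 15, median 0.29), neutrophil (15 of 16, median 0.21) and stellate cell genes (14 of 18, median 0.18) were higher, and the call of each is lost with an estimated correlation (adjusted p = 0.627 to 0.683). Hepatocyte values overlapped between the genotypes, with P3 knockout 1 the lowest of the 7 libraries. The same test called antigen presentation (13 of 16 higher, median 0.18), hypoxia and glycolysis (18 of 22, median 0.18), proliferation (23 of 32, median 0.10) and mitochondrially encoded genes (10 of 12, median 0.21), with adjusted p = 0.627 to 0.683 with an estimated correlation. P3 knockouts were 1 female and 3 males by Xist and Ddx3y, and P3 controls 2 females and 1 male.

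At P42 the same question was asked in young adults. Slc26a10 fell from 73.5 ± 16.7 to 9.58 ± 0.414 FPKM (SD, n = 3 each; log2 change -2.79, SE 0.18, limma adjusted p = 0.00382). Il13ra2, a decoy receptor for interleukin 13, fell from 15.2 ± 2.74 to 1.18 ± 0.384 FPKM (log2 change -2.89, SE 0.22, limma adjusted p = 0.00546). These were the 2 calls among 12838 genes, while 1894 genes had an unadjusted p under 0.05 and 642 are due by chance. With the replicate block 146 genes were called, 30 higher and 116 lower, both of these among them. Without P42 control 2 there were 15 calls and without knockout 1 there were 6, 1 fit over all groups gave 177, a covariate for Xist 22, and a covariate for other cell types 0. Rescaling every library to the same FPKM sum gave 393 calls, 240 higher and 153 lower, against 0 higher and 2 lower in the values as deposited. That rescaling raised the median SE from 0.206 to 0.331 and limma's prior degrees of freedom from 4.11 to 48.9, and fewer genes, 1761, then had an unadjusted p under 0.05.

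The angiocrine genes Wnt9b, Rspo3 and Wnt2, which endothelial cells of the central vein and sinusoids supply to hepatocytes, did not pass at P42 as designed and passed with the replicate block, and Wnt9b and Rspo3 also with the Xist covariate. Wnt9b measured 10.3 ± 4.70 FPKM in controls and 1.60 ± 0.496 in knockouts (log2 change -2.07, limma adjusted p = 0.104, blocked 0.0419). Rspo3 measured 15.1 ± 6.06 and 3.05 ± 1.16 FPKM (log2 change -1.96, limma adjusted p = 0.104, blocked 0.0402). Wnt2 measured 64.3 ± 23.7 and 25.3 ± 7.32 FPKM (log2 change -1.29, limma adjusted p = 0.142, blocked 0.0419). Other genes that did not pass as designed and were lower with the block were the venous receptor gene Ackr1 (-2.11), Gvin1 (-1.37), Rab3b (-2.30), Pgm5 (-2.39), Tspan18 (-1.45), the arterial connexin gene Gja5 (-1.99), the tight junction gene Cldn5 (-1.02) and Zfpm1 (-1.08). Higher with the block, and not called as designed, were the granule genes Mpo (2.45), Prg2 (3.26) and Elane (2.30), the hepatocyte genes Tat (2.45) and Cyp4a10 (2.76), the immediate early gene Egr1 (2.70) and Slc25a25 (1.46). Trim34b (2.16), Errfi1 (1.54) and Alas1 (1.04) passed in neither fit, nor did Klf4 (0.69), Klf2 (0.35) and Lyve1 (0.20). Trim5 and Trim12a were listed at 0 in P42 knockout 1 and measured 2.35 and 2.49, and 20.76 and 18.86 FPKM, in the others, against 5.54 to 6.55 and 40.16 to 55.32 in controls.

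Most endothelial lists fell at P42 in the camera test. Arterial genes (camera adjusted p = 0.0565) and lymphatic genes (camera adjusted p = 0.560) were not called. All 22 pan-endothelial genes were lower (median log2 change -0.63, 20 adjusted over the list alone, 0 over all genes), with an adjusted p of 0.556 with an estimated correlation. The counts were 24 of 29 for sinusoidal identity (median -0.63, 19 over the list alone), 12 of 13 for venous genes (median -0.78, 9), 17 of 18 for junctions (median -0.49, 5), 18 of 20 for angiocrine factors (median -0.58, 8) and 19 of 21 for basement membrane (median -0.63, 1). Continuous capillary genes (15 of 18 lower, median -0.61), BMP and TGF-beta signalling (19 of 20, median -0.30), the HEG1-CCM pathway (19 of 22, median -0.27) and the interferon response (23 of 25, median -0.33) were called lower as well. With an estimated correlation, the adjusted p of these lists lay between 0.556 and 0.687. The median of all genes was -0.12, and median-ratio scaling moved it by 0.13 to 0.0055, while the same-sum rescaling moved it by -0.18.

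Lists of other cells and of stress rose at P42 in the same test. Hepatocyte genes were higher in 21 of 21 (median 1.64, 9 over the list alone), periportal genes in 15 of 16 (median 1.94, 11), neutrophil and myeloid genes in 12 of 12 (median 1.89, 10) and dissociation and immediate early genes in 19 of 23 (median 0.99, 14 higher and 1 lower over the list alone). Inflammatory genes were higher in 13 of 18 (median 0.57). Each of these has an adjusted p = 0.556 with an estimated correlation. Alb, the main hepatocyte transcript, measured 586.93, 1713.13 and 2733.49 FPKM in controls and 2387.63, 15972.5 and 6571.53 in knockouts, so the groups overlapped while the knockout was higher in each of the 3 numbered pairs. Stellate cell genes were lower in 17 of 17 (median -0.74, adjusted p = 0.687 with an estimated correlation). Also called higher were Kupffer cell genes (16 of 17, median 0.15), cholangiocyte genes (5 of 5, median 0.91), proliferation (20 of 31, median 0.15), cholesterol synthesis (15 of 20, median 0.21) and mitochondrially encoded genes (12 of 12, median 0.91). With an estimated correlation their adjusted p was 0.556 to 0.687. The sexes were balanced, with 1 female and 2 males in each group by Xist and Ddx3y.

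**Figure D2:**
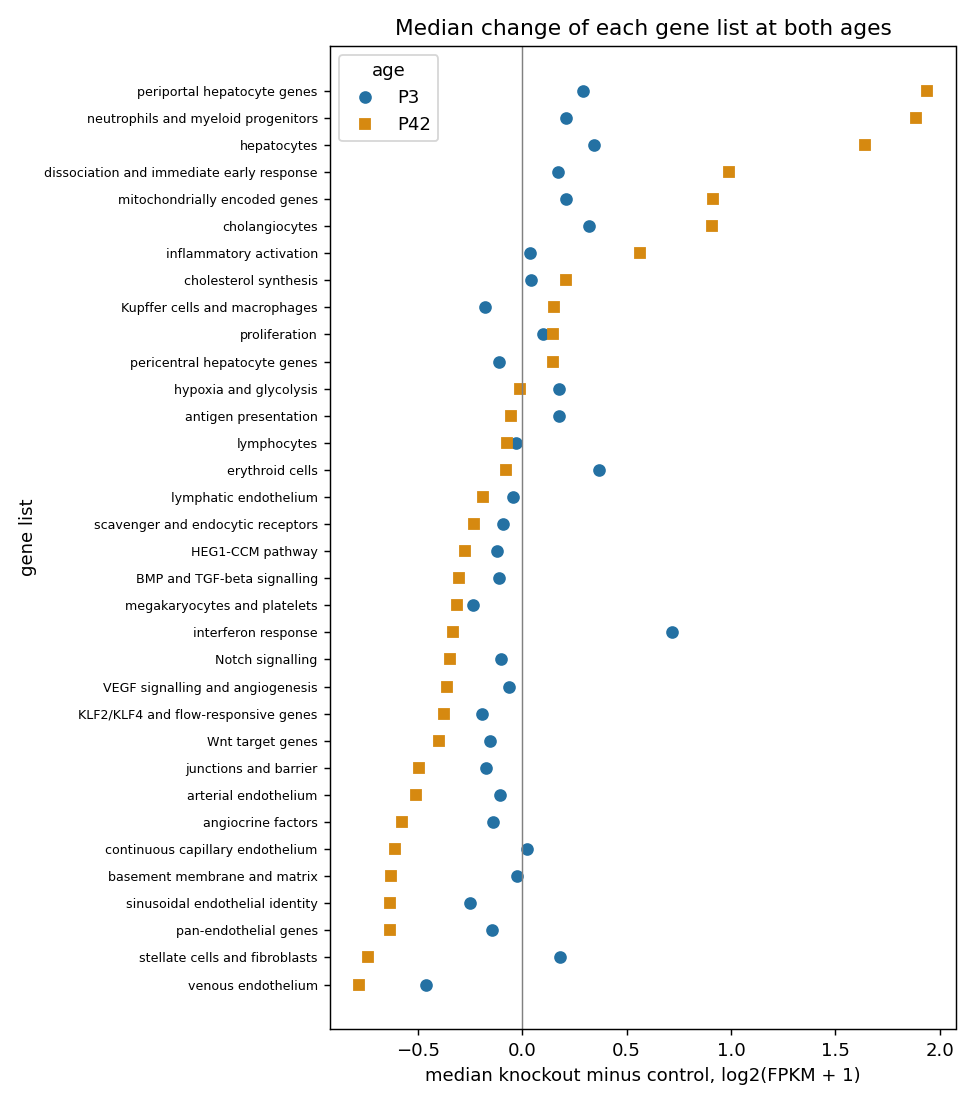
Median knockout minus control change in log2(FPKM + 1) of each of the gene lists other than the sex-linked genes, on the horizontal axis, with lists on the vertical axis, for P3 (circles) and P42 (squares). The interferon list lies at 0.72 at P3 and at -0.33 at P42, and hepatocyte genes at 0.34 and 1.64.

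**Figure D3:**
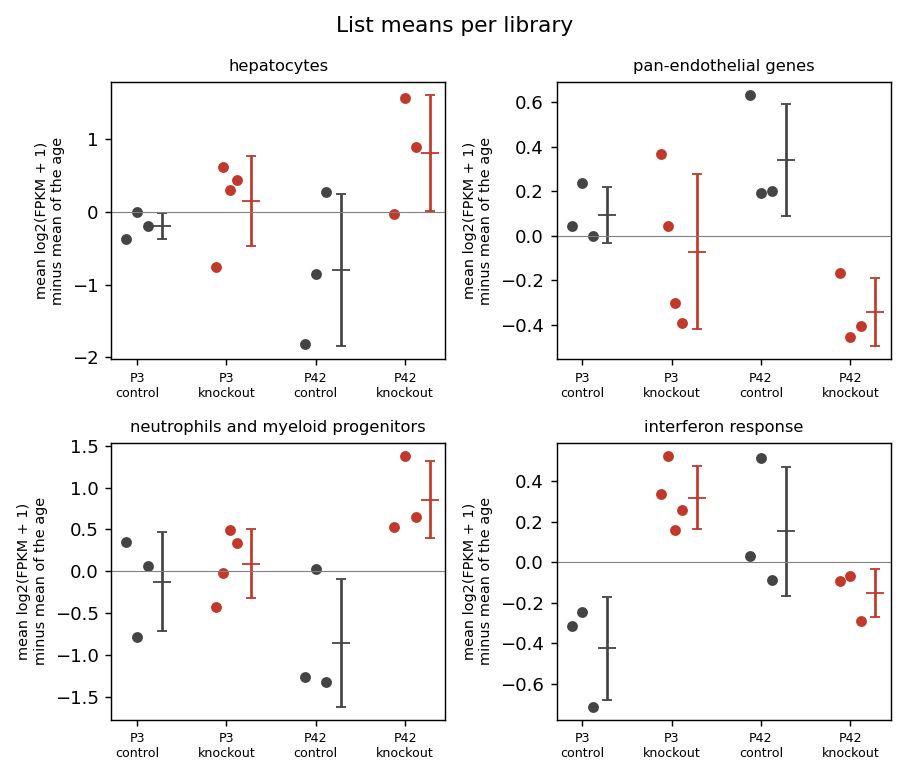
Mean log2(FPKM + 1) of 4 lists per library on the vertical axis, as the difference from the mean of all libraries of that age, by group on the horizontal axis; points are libraries and the bar is the mean with its SD. All P3 knockouts lie above all P3 controls for the interferon list, while hepatocyte values overlap between genotypes at both ages, with the knockout higher in each numbered pair at P42.

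Whether the genotype effect differed with age was tested by the interaction. No gene passed in limma among 13246, with 1011 at an unadjusted p under 0.05. With the block among the P42 samples 4 passed: Hspa1a higher, and Il13ra2, Tgtp2 and Adgrg1 lower, the last named after its value was seen. Without it, Il13ra2 had an interaction of -2.70 (limma adjusted p = 0.0717), Tgtp2 of -1.77, Xaf1 of -1.43, Cldn5 of -1.19, Slc26a10 of -1.36, Hspa1a of 2.51, Alas1 of 1.23, Ugt1a9 of 2.21, Insig2 of 1.01 and Mpo of 2.30. At P3 Il13ra2 measured 0.63 FPKM in controls and 0.44 in knockouts, too low to show a fall like that at P42. Ugt1a9 measured 0.37 and 0.30 FPKM there. The interferon list differed between the ages in the camera test, with 25 of 25 members lower in the interaction (median -1.04, 23 adjusted over the list alone). Its adjusted p was 0.418 with an estimated correlation. The calls of both ages shared Slc26a10. At an unadjusted p under 0.01, 33 genes were lower at both ages, among them Heg1, Wnt2, Wnt9b, Cdh13, Rab3b and Sox17, and 3 were higher. If genes were independent, 2.9 lower ones would be due (exact hypergeometric p = 1.41e-26). Genes share deviations across libraries, so this p is no measure of the spread between samples. A set of genes that move together could give such an overlap, and no relabelling of samples was done for it. Across 12210 genes, which are not independent replicates, the changes had Spearman's rho of 0.296, and 61.4 percent had the same sign.

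Between P3 and P42, proliferation, erythroid and neutrophil genes fell in the control libraries, and sinusoidal and macrophage ones rose. Age and any batch of preparation cannot be told apart here, and the sexes of the controls differed between the ages. Nor can changes within cells be told from changes in the mix of sorted cells. In limma 6851 of 13168 genes passed, 2106 higher and 4745 lower at P42. The imprinted gene H19 fell from 794 ± 111 to 0.19 ± 0.017 FPKM (SD, n = 3; log2 change -9.37). Igf2 (log2 change -7.28), the fetal liver gene Afp (-9.22), Mpo (-6.86), Prg2 (-6.71) and Hba-a1 (-6.71) fell too. Cstdc4, Cstdc5, Stfa2 and Stfa3 fell too, and Cstdc5, Stfa2 and Stfa3 are listed at 0 at P42. Mup3 (6.69), Mup15, Mup20, Mup22, Serpina3k, Mug1 and Hamp2, all made by hepatocytes, rose, as did Igha (6.20), Cxcl13 (4.90) and Xdh (5.06). The hepatocyte list did not pass, with 16 of 22 members lower (median -0.71), 5 called lower and 3 higher. All 32 proliferation genes fell (median -2.86; Mki67 by 3.71), as did 18 of 18 erythroid genes (median -3.51) and 14 of 16 neutrophil genes (median -5.56, with 1 higher). Of 29 sinusoidal genes 25 rose (27 adjusted over the list alone, median 1.42; Fcgr2b 2.64, F8 2.19, Dnase1l3 2.63), as did 19 of 22 pan-endothelial genes (median 1.09, with 1 lower) and 24 of 25 interferon genes (median 1.28). Markers of other cells moved with them: 12 of 17 Kupffer cell and macrophage genes rose (median 0.88, with 1 lower). The angiocrine gene Bmp6 rose by 3.74 on the log2 scale. All of these list calls are lost with an estimated correlation (adjusted p = 0.473 to 0.474), and fry called 19 of the 35 lists. The count splits by direction differed with scaling: 3185 higher and 3282 lower with median-ratio scaling, 3362 and 3192 with quantile normalization, 2234 and 3188 with the same-sum rescaling, and 3122 and 3118 without mitochondrial genes. The median of all genes was -0.24, and these scalings moved it by 0.14 to 0.27, so proportions of rises and falls are relative to the scaling.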

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

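The tests of the 3 patterns below were chosen after the results were seen, as were the effect averaged over both ages and all of its splits. The other counts over splits of the samples were set before those splits were fitted.

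Among 62 values tested in the 4 P3 knockouts, 5 had a sample far from the other 3, and chance gives about 1 in 20. P3 knockout 1 had 462 FPKM of Lyve1 against 178, 181 and 192, and 37.1 FPKM of Ikzf3, above the other 3. The mean log2 value of its sex-linked genes was 1.315, below the other 3, and it is the female of this group by Xist. P3 knockout 4 had 17.1 FPKM of Ceacam1, above the other 3. P3 knockout 2 had 0.70 FPKM of Igkv12-38, which is listed at 0 in the other 3.

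By the interaction test with a preset correlation, 16 lists differed between the ages in their genotype effect, and 0 did with an estimated correlation. The median interaction was above 0 for hepatocytes (1.22), periportal (1.53) and pericentral hepatocyte genes (0.21), Kupffer cells (0.28), neutrophils (1.43), inflammatory activation (0.40), immediate early genes (0.86) and mitochondrially encoded genes (0.73). It was below 0 for angiocrine factors (-0.44), sinusoidal identity (-0.36), continuous capillary genes (-0.50), pan-endothelial genes (-0.49), stellate cells (-0.86), interferon response (-1.04), basement membrane (-0.58) and junctions (-0.38).

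Other splits of the samples were fitted in the same way, and at P3 chance could not be excluded: 2 of 35 splits gave at least the 3 genes called, and the highest other gave 5. Nor could it for the 15 lists called at P3, where 14 of the 35 splits gave as many, with a highest other of 26. At P42 the 10 splits are too few for a share under 0.05: the real split gave 2 genes and the highest other 1, and for lists 21 against 25, with 3 splits as large. Among the 4 splits that part all 3 P42 pairs, the blocked fit gave 146 genes in the real one and 0 in the highest other, again too few splits. The other 6 splits leave a pair on the same side, and without the block they gave 0 or 1 gene. For the interaction, all of 100 drawn splits gave at least its 0 genes, as any split must, so this count tests nothing. Of the 99 others 67 gave 0 (median 0) and the highest 513, and that 1 split points to a structure of the samples, whose source was not tested. For its 16 lists, 47 splits gave as many, with a highest other of 28. In the age comparison the 10 splits are too few: the real one gave 6851 genes and the highest other 5, and for lists 20 against 27, with 6 as large. For the genes of the effect averaged over both ages, 1 of 100 splits, the real one, gave the 145 called, and the highest other gave 132. Of 100 splits that part all 3 P42 pairs, 1 gave as many and the highest other 124, and with the block 2 gave at least the 540 called and the highest other 1018. These shares are under 0.05, but they bear on the count and not on single genes. They also do not allow for the choice of this effect after the data were seen. The margin was small, and without P3 control 3 or P42 control 1 the count was 50. Chance is thus not excluded for this count. Nor can it be excluded for the 22 lists of this effect, with 16 of 100 splits as large and a highest other of 25.

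At P42, lists of hepatocytes, myeloid cells and immediate early genes were higher and most endothelial lists lower in knockouts. A lower share of endothelial cells alone would raise all other cell types, and stellate cell genes went the other way (median -0.74, the lowest of the 8 lists of other cell types). Megakaryocyte (-0.31), erythroid (-0.08) and lymphocyte medians (-0.07) did not rise either. Hepatocyte (1.64), neutrophil (1.89), cholangiocyte (0.91) and Kupffer cell medians (0.15) did. But the stellate list score varied widely over libraries, with means of 0.38 (SD 0.76) in P42 controls and -0.38 (SD 1.02) in P42 knockouts. Erythroid and lymphocyte scores varied too (SD 0.33 to 0.66), and the megakaryocyte list held 4 genes. A lower share of endothelial cells is therefore not excluded. A larger share of mitochondrial RNA lowers all other genes alike, so it raises none, and it does not account for the whole endothelial fall, since the gap between pan-endothelial and other genes differed by -0.51 (SE 0.146) in knockouts. Hepatocyte RNA carried into the sort is a candidate explanation for the hepatocyte part. That 100 percent of that list was higher is the pattern itself and no separate test of this. Mean scores were -0.81 in P42 controls and 0.81 in P42 knockouts for hepatocyte genes, and -0.11 and 0.11 for pericentral ones. Genotype, a lower share of endothelial cells, and handling of the tissue stay open.

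Trim34b was higher and the neighbouring Trim5, Trim12a and Gvin1 lower in knockouts, all on chromosome 7 at 104263386 to 106215340, near Lyve1 at 110850607. The Gvin1 groups overlapped at P3, with 6.50 to 14.53 FPKM in controls and 4.54 to 8.06 in knockouts. The values argue against an interferon response as the source for Trim34b, which was higher by 2.16 at P42, where the interferon median was -0.33. But Trim34b passed in neither P42 fit. The interferon scores, relative to the mean of the age, were 0.15 (SD 0.32) in P42 controls and -0.15 (SD 0.12) in P42 knockouts. A strain variant linked to the Lyve1-Cre allele may be the source, but this cannot be told apart: 6 genes near Lyve1 were called in the averaged effect (Fisher's exact p = 0.0227), all of them Trim genes, Gvin1 or Tpbgl, and with the 15 genes of these kinds there left out 0 of 184 were called, 1.94 being due (p = 0.270). Reads moved between paralogs also cannot be told apart: the summed Trim signal differed by -0.75 at P42, where the groups did not overlap, and by -0.20 at P3, where they did. P42 knockout 1, where Trim5 and Trim12a were listed at 0, had 9.12 FPKM of Trim34b, against 3.59 and 2.68 in the other P42 knockouts. Moved reads or a linked variant could give this, and 1 library cannot tell them apart, so the size of the Trim34b change at P42 is uncertain. The log2 Trim sum of P42 knockout 1 was 6.70, against 6.95 and 6.77 in the other P42 knockouts. Genotype itself stays open.

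The interferon list was higher in all 4 P3 knockouts than in all 3 controls. Its score differed by 0.74, and unequal sexes do not account for it, since with Xist as covariate the difference was 0.72 (SE 0.187). The neutrophil list was also called higher (median 0.21), but with a covariate for neutrophils the difference was 0.78 (SE 0.156), for macrophages 0.86 (SE 0.0759) and for lymphocytes 0.71 (SE 0.114). So the amount of these cells, as read from their markers, does not account for it in these fits on few libraries. The marker scores differed little between genotypes (0.22, -0.19 and -0.05). An interferon response within these cells at an unchanged amount would not be seen by such fits and stays open. Immune cells outside these lists stay open. The genotype is a hypothesis for it, untested beyond these samples, and litter, infection or handling were not recorded in the labels used here. Within the genotype, loss of Heg1 and presence of Cre cannot be told apart, as no control carried Cre.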

How the results depend on the processing

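Alternatives chosen after the data were seen are leaving out the mitochondrial genes, fry, the covariates for the lists, the P42 block in fits over all groups, and every setting of the averaged effect. Of the values of single named genes, 1548 kept their direction and side of the threshold, 125 newly passed and 118 no longer passed, and of the list values 376 were kept and 136 no longer passed. Depth is only estimated here, and no limit for low genes was drawn from it. Except where a reason is given, the cause was not tested.

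The P3 count of 3 genes became 1 with a pseudocount of 0.1, quantile normalization, no variance trend, a covariate for other cell types or one for Xist, and 5 with a mean FPKM of at least 5, where fewer genes were tested. The P42 count of 2 became 1 with no filter, 4 with a mean FPKM of at least 5, 7 with robust eBayes, 22 with the Xist covariate, 0 with the covariate for other cell types and 177 in 1 fit over all groups, which has more residual degrees of freedom. It became 393 with the same sum in every library, where limma's prior degrees of freedom went from 4.11 to 48.9. Heg1 at P42 passed with that sum (-1.98, adjusted p = 0.000304) and in 1 fit over all groups (-1.81, adjusted p = 0.00934). Over the alternatives that leave no replicate out, the interaction gave 2 genes with the same sum, 1 with median-ratio scaling, quantile normalization or no mitochondrial genes, and otherwise 0, the block apart. The averaged effect gave 270 genes without mitochondrial genes, 96 with no filter, 75 with the Xist covariate and 10 with the covariate for other cell types, against 145. Of 15 lists at P3 and 21 at P42, 0 were called with an estimated correlation and 0 with fry. The overlap of calls, 1 gene, was 36 at an unadjusted p under 0.01 and 0 with a pseudocount of 0.1.

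With the replicate block the P42 count was 146 by either number, Heg1 passed (-1.81, adjusted p = 0.0435), the interaction gave 4 genes and the averaged effect 540, while no list call at P42 changed. At P3 the numbers in the titles and the library numbers differ and neither pairs the samples (correlations -0.108, -0.273 and 0.321, and 0.055, 0.421 and 0.253). The replicate block by either number gave 0 genes there, and 24 lists were called with the title numbers.

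Lyve1 at P42, 0.20, was -0.0012 with the same sum, -0.092 without P42 control 2 and -0.033 without P42 knockout 1, and at most 0.58 without P42 control 1. The mitochondrial list at P3 was -0.022 with quantile normalization, and the neutrophil list at P3 was -0.13 with the Xist covariate and -0.19 without P3 control 3, against 0.52 without P3 control 2. With the covariate for other cell types at P42 the Kupffer cell median was -0.19, and the stellate cell list, at -0.098, turned in its test and not in its median.

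With each replicate left out in turn, counts ranged from 1 to 4 at P3, 2 to 15 at P42, 0 to 1 in the interaction, 5229 to 6527 in the age comparison and 50 to 418 in the averaged effect. Lists ranged from 8 to 26 at P3 and from 17 to 22 at P42. Heg1 ranged from -0.75 to -0.61 at P3 and from -2.002 to -1.49 at P42.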

Other observations

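The effect averaged over both ages and the tests of the scores below were chosen after the data were seen. In the averaged effect 145 of 13246 genes passed in limma, 22 higher and 123 lower in knockouts. Slc26a10 fell (log2 change -2.11, SE 0.12, adjusted p = 2.32e-06), as did Rab3b (-1.77), Pet117 (-1.72), Pgm5 (-1.69), Ly6c1 (-1.61), the growth factor receptor gene Fgfr3 (-1.61), Wnt9b (-1.59), Fndc1 (-1.52), Cdh13 (-1.43) and the neuropeptide gene Nts (-1.41). Trim34b rose (2.10), as did the endothelial tip cell gene Esm1 (1.29), Susd4 (0.78), Gbp10 (0.76), the chemokine gene Cxcl9 (0.72), Uck2 (0.56) and Zbtb8os (0.36). Ier3, Pvt1 and Odc1 had log2 changes of 0.63, 0.56 and 0.72 and did not pass. The count was 540 with the block among the P42 samples and 10 with a covariate for other cell types. Without single libraries it was 50 (P3 control 3 or P42 control 1), 60 (P3 knockout 4), 62 (P3 control 2 or P42 knockout 4), 63 (P42 knockout 2), 66 (P3 knockout 3), 72 (P3 control 4), 294 (P3 knockout 1) and 418 (P42 knockout 1). In camera 22 lists were called, 13 higher and 9 lower, 0 with an estimated correlation (lowest adjusted p = 0.324), and fry called 9.

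Among lists that camera called at neither genotype comparison, arterial genes had a median log2 change of -0.10 at P3 and -0.51 at P42, lymphatic genes -0.04 and -0.19, Notch signalling -0.10 and -0.35, VEGF signalling -0.06 and -0.36, Wnt target genes -0.15 and -0.40 and scavenger receptors -0.09 and -0.23. Megakaryocyte genes had -0.24 and -0.31, lymphocyte genes -0.03 and -0.07, pericentral hepatocyte genes -0.11 and 0.15 and sex-linked genes 1.23 and 0.01. The median and the test differed in sign at P3 for continuous capillary genes (median 0.02, test lower), and at P42 for lymphatic, erythroid (-0.08), lymphocyte, antigen presentation (-0.05) and hypoxia genes (-0.01), whose tests were higher.

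The hypothesis that pericentral hepatocyte transcripts were lower relative to periportal ones, beside lower Wnt2, Wnt9b and Rspo3, was tested on the difference of the 2 list means. It differed by -0.45 between knockouts and controls at P3 (exact permutation p = 0.0571) and by -1.48 at P42 (exact permutation p = 0.1, the smallest possible there). Permuting genotype within ages gave an exact two-sided p = 0.00286 for both ages together, and 0.00143 without Wnt feedback genes, the smallest that 700 permutations can give. These permutations, and those at P42 alone, did not keep the numbered P42 pairs, so these p-values do not hold if the numbers pair the samples. With the hepatocyte score as covariate the difference was -0.35 (SE 0.210) against -0.93, and without Wnt feedback genes -0.46 (SE 0.278) against -0.86. The mean of Wnt2, Wnt9b and Rspo3 relative to pan-endothelial genes was lower by the same permutation (exact p = 0.00286; adjusted p = 0.00286 for each of the 3 scores). That Wnt score was not fitted with the hepatocyte score. At P3 alone the amount of hepatocyte RNA, as a linear covariate on few libraries, does not account for the pericentral against periportal difference (-0.37, SE 0.122, against -0.45). Without Wnt feedback genes it was -0.47 (SE 0.140) against -0.48. At P42 the amount of hepatocyte RNA cannot be told apart with 6 libraries: -0.30 (SE 0.570) against -1.48, which a bound without the SE, used at first, would have taken as explained. Without Wnt feedback genes the P42 difference was -0.46 (SE 0.765) against -1.30.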
